A study of Mus musculus with 10 samples.

How the data were processed

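The series holds 10 mouse oocyte libraries at metaphase II, 5 control and 5 treated with TubA, with groups and replicate numbers taken from the sample titles. Per the labels' protocols, germinal vesicle oocytes were collected from ovaries, matured at 37 °C in 5% CO2 for 16 h, with TubA at 0.1 µg/mL for 16 h in the treated group, then amplified as single cells with Smart-seq2, a full-length protocol that copies polyadenylated RNA, and sequenced on a HiSeq 2000. Per the submitters' processing notes, the genome build was mm10 and the tools included Bowtie 0.12.2. The program that turned alignments into abundances and the annotation release are not given in the sources used here. The labels do not say whether strand was kept, so reads of a gene and of an antisense partner cannot be told apart.

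The deposited files hold TPM, 1 value per Ensembl transcript and library. The unit was read from the values, since those of each library sum to 1000000. Values down to 3.2e-11 TPM occur, as from a program that divides reads between transcripts by estimation, so transcripts with near-identical copies can exchange reads from library to library. TPM keeps no depth, and no count was recovered, so no counting interval or floor is given, and the precision is that of the spread between libraries. No pair of files held identical values. A low-abundance value of exactly 0 is reported as listed at 0.

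Transcripts were summed to genes with the GENCODE M21 annotation of GRCm38, which is the same assembly as mm10, after dropping version numbers. Of the transcripts, 113492 matched and 1778 did not. The unmatched ones held between 0.531% and 0.753% of each library's TPM and were left out, without rescaling. This gave 35501 genes, of which 22278 were above 0 in at least 1 library. Coordinates are those of that annotation. Summing was done with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

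The test for TubA against control was limma 3.58.1 (R 4.3.3) on log2(TPM + 1), with a pseudocount of 1, for the 11664 genes with a mean of at least 1 TPM over all libraries, with an intensity trend, robust moderation and Benjamini-Hochberg adjustment at 0.05. All 10 libraries entered the fit without covariates. Differences are TubA minus control on the log2(TPM + 1) scale, which understates the change of low genes. The test was written down before the data were examined, with a count model for count files and this form for normalised values, and the latter applied. So were the gene lists, the rule for named genes and the alternatives. Tested on 20 simulated data sets with the means and spreads of these 11664 genes and 200 changed genes, the fit recovered 32.2% of genes changed 2-fold and 82.2% of genes changed 4-fold, and 5.09% of its calls were false on average. The changed genes were drawn from those with a mean log2(TPM + 1) of at least 3, so the shares do not cover low genes. The simulated genes varied independently and normally, without the library sets described below, so the shares may differ in the real data.

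For 32 gene lists with at least 5 genes tested, camera was run with a preset correlation of 0.01 and with an estimated correlation, and fry beside it, with adjustment over the 32 lists. Lists shifted by 0.5 log2 units in simulated data were found in 20 of 20 runs, and 0 of 580 unshifted lists were called. These simulated genes varied independently, unlike genes of one pathway. Of the lists, 3 are markers of other cell types of the ovary and blood. Library measures were compared with an exact two-sided permutation test over the 252 assignments of 5 of 10 libraries.

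The rule for named genes takes the 12 genes of largest increase and the 12 of largest decrease among genes past the threshold, with no overlap between groups and at least 10 TPM in the higher group, leaving out predicted loci and pseudogenes. Since too few genes passed, the genes of smallest p under the other conditions filled the places, and 1 of these is not reported here. It adds up to 4 members per list past the threshold, or otherwise the 2 most abundant, then Hdac6, Tuba1a, Tuba1b, Tuba1c and Tubb5, and Zp3, Gdf9 and Mos as levels of the cell type. Sharing of sequence was measured as the percentage of a gene's words of 31 bases that also occur in another gene listed above 0, and a gene sharing at least 20% was counted as a copy.

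The alternatives were other pseudocounts, filters and scalings, weights for libraries, the replicate number as a block, and leaving out each library in turn. Added after seeing the data were the 2 sets of libraries found by complete-linkage clustering of correlations (as a term, and each set alone, with the preset and with an estimated correlation), the addition of nuclear copies to the mitochondrial genes, and the leading principal component of the residuals as a term. The set is not a label of the submitters and was found from the same values.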

Results

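The series holds single-cell transcriptomes of mouse oocytes at metaphase II, the stage at which a mature egg waits for fertilisation. Germinal vesicle oocytes from the ovaries of ICR mice aged 6 to 8 weeks were matured in culture for 16 h. There were 5 libraries labelled control and 5 treated with TubA at 0.1 µg/mL for 16 h. TubA is a name in common use for tubastatin A, an inhibitor of the tubulin deacetylase HDAC6, although the labels do not spell the name out. The comparison asks which transcripts differ when oocytes mature in the presence of this agent. Values were in TPM, an abundance scaled to the same total in every library, which carries no sequencing depth, so the depth of each library is unknown and no counting interval can be given. The labels describe each library as a single cell and name no animal or culture. Thus n counts oocyte libraries, and p-values measure only the spread between these libraries, which may be technical.

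The libraries of both groups carried the transcripts of mature oocytes at high levels. Gdf9, a growth factor secreted by oocytes, stood at 5587 ± 812 TPM in control and 6343 ± 845 TPM with TubA (mean ± SD, n = 5 in each group, control first, here and below). Zp3, a protein of the egg coat, stood at 2592 ± 1989.5 and 2809 ± 3082 TPM. It ranged from 406 to 5363 TPM among control libraries and from 750 to 8123 TPM among TubA libraries, so its mean is poorly fixed. Mos, the kinase that holds the metaphase II arrest, stood at 309.6 ± 38.9 and 352 ± 71.2 TPM. Hdac6 itself was low, at 4.34 ± 2.66 and 5.60 ± 3.20 TPM, and did not pass the test (limma, log2 difference 0.33, unadjusted p = 0.46). Among the tubulin genes, Tubb5 stood at 26.0 ± 15.8 and 38.0 ± 26.0 TPM and Tuba1a at 5.30 ± 3.62 and 3.15 ± 1.57 TPM. Tuba1b stood at 17.1 ± 8.23 and 16.9 ± 11.1 TPM and Tuba1c at 259 ± 121 and 219 ± 49.4 TPM. Between 63.7% and 78.6% of the sequence words of these 3 alpha-tubulin genes also occur in other listed genes, so the split of reads between them is uncertain. The number of genes at or above 1 TPM was 11287 ± 444 in control and 11167 ± 415 with TubA, a difference within the spread between libraries (exact two-sided permutation p = 0.68).

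Transcripts of the mitochondrial genome lay lower with TubA as a list by camera with a preset correlation of 0.01 (adjusted p = 6.0e-11 over 32 lists). This call was lost when the correlation was estimated from the libraries (adjusted p = 0.42 with an estimated correlation). The 6 genes that were lower when adjusted over the list alone lie side by side, from mt-Nd3 to mt-Cytb, and encode subunits of respiratory complex I and cytochrome b. The ends of mt-Nd4l (9877 to 10173) and mt-Nd4 (10167 to 11544) overlap, as do those of mt-Nd5 and mt-Nd6 (13552 to 14070). Such neighbours may share reads, as the strand is not known, so the 6 genes are not fully separate measurements. mt-Nd3 (mitochondrial chromosome, 9459 to 9806) had 297 ± 48.3 TPM in control and 143 ± 29.1 TPM with TubA. mt-Nd5 (11742 to 13565) had 99.5 ± 8.98 and 48.6 ± 12.3 TPM. mt-Nd4 stood at 684 ± 118 and 353 ± 91.1 TPM and mt-Nd4l at 781 ± 404 and 374 ± 109 TPM. mt-Nd6 stood at 208 ± 59.96 and 101 ± 44.5 TPM and mt-Cytb at 1956 ± 558 and 1139 ± 335 TPM. In mt-Nd3, mt-Nd4l, mt-Nd4 and mt-Nd5 every TubA library lay below every control library. The 7 genes from mt-Nd1 to mt-Co3 had log2 differences between -0.42 (mt-Co3) and 0.04 (mt-Nd1). The most abundant of them as listed, mt-Atp6 and mt-Co1, had 4009 ± 1810.0 and 3272 ± 1337 TPM and 1835 ± 321 and 1859.5 ± 608 TPM. The mitochondrially encoded genes, a list fixed before the data were examined, had a median log2 difference of -0.42 (12 of 13 genes negative). No member passed over all genes tested (limma), and 6 were lower when adjusted over the list alone, namely mt-Nd3, mt-Nd4, mt-Nd4l, mt-Nd5, mt-Nd6 and mt-Cytb. The fry test of limma, which asks whether the genes of a list move on balance in a single direction, gave an adjusted p = 0.60 over the lists. Its mixed test, which counts changes in either direction, gave an adjusted p = 0.048. An exact two-sided permutation test of the list's mean per library gave p = 0.071 (0.85 when adjusted over the lists). The 13 genes together held 1.27 ± 0.317% of the TPM in control and 1.01 ± 0.354% with TubA (exact two-sided permutation p = 0.25). Annotated copies on chromosome 1 share 98.1% of the sequence words of mt-Nd3, 98.9% of those of mt-Nd4l and 62.8% of those of mt-Nd4, so these 3 levels are uncertain. So are those of mt-Atp6, mt-Co1 and mt-Co2, which share 99.5%, 63.9% and 100% of their words, and of which mt-Atp6 has a copy listed at a mean of 3570 TPM and mt-Co1 copies at 1464 TPM. With copies added, the log2 difference was -0.36 for mt-Atp6, -0.12 for mt-Co1 and -0.18 for mt-Co2. mt-Nd5, mt-Nd6 and mt-Cytb had no copy sharing 20% or more.

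**Figure D1:**
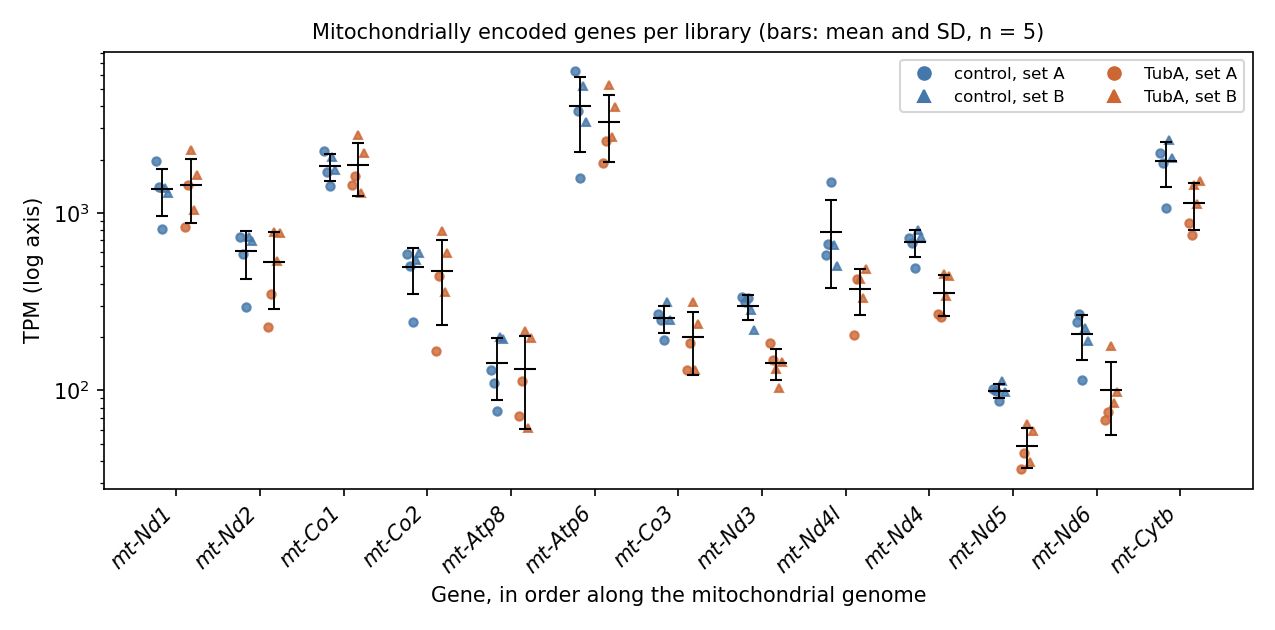
TPM of the 13 mitochondrially encoded genes (log axis) in each library, in their order along the mitochondrial genome, coloured by group and shaped by library set, with black bars for the mean and SD of 5 libraries. TubA libraries lie below control libraries in mt-Nd3, mt-Nd4l, mt-Nd4 and mt-Nd5 (99.5 against 48.6 TPM on average for mt-Nd5).

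Hardly any single gene could be told apart between TubA and control oocytes, and none of the mitochondrial list. Of 11664 genes tested with limma on log2(TPM + 1), 1 passed an adjusted p of 0.05. It was the processed pseudogene Rpl36-ps1 (ENSMUSG00000081318, chromosome 11, 116504536 to 116504838, GRCm38). Rpl36-ps1 was listed at 0 in all 5 control libraries and at 7.75, 8.20, 6.83, 4.30 and 3.93 TPM in TubA replicates 1 to 5 (limma adjusted p = 0.0024). It falls outside the rule for named genes and was chosen after its values were seen. The call ended with a filter at a mean of 5 TPM, which leaves the gene out, and with the replicate number as a block (limma adjusted p = 0.092). At an unadjusted p under 0.05 stood 293 genes, 132 higher and 161 lower with TubA, against 583.2 by chance alone. Of 271 such genes without control replicate 1, 83 were higher with TubA, and of 452 without control replicate 3, 250 were higher (limma). The libraries of both groups did not overlap in 53 genes (22 higher, 31 lower), where chance gives 0.794% of genes or 92.6. The 95% interval of the difference lay inside a 2-fold change of TPM + 1 in either direction for 6654 genes (57.0%). In low genes this bound allows a larger change in TPM. The median standard error was 0.33 log2 units.

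The 24 genes taken by the fixed rule had no overlap between groups and at least 10 TPM in the higher group, and none passed the threshold (lowest limma adjusted p = 0.64). Among the 12 higher with TubA, Pnpla3, a lipid droplet acylhydrolase gene (chromosome 15, 84167837 to 84187236), was the most abundant. It stood at 1686 ± 238 and 3197 ± 1360.3 TPM (log2 difference 0.83, limma unadjusted p = 0.0059). TubA replicates 1 and 2 had 5121 and 4107 TPM, the other TubA libraries 1953 to 2569 TPM, and control libraries at most 1943 TPM. The log2 difference of Pnpla3 was 1.55 within library set A and 0.28 within set B (sets described below). Zfpm1, a cofactor of GATA transcription factors, had the smallest p of the 12, at 0.581 ± 0.381 and 11.8 ± 10.7 TPM (log2 difference 2.56, limma unadjusted p = 0.00078). The cochaperone gene Dnajc7 stood at 36.5 ± 7.19 and 61.1 ± 19.9 TPM. Dppa2, a chromatin factor of pluripotent cells, stood at 69.2 ± 9.81 and 101 ± 27.1 TPM. The DNA polymerase delta subunit gene Pold3 stood at 279 ± 6.17 and 352 ± 77.1 TPM (log2 difference 0.31, and 0.19 without TubA replicate 1). The log2 difference was 0.95 for Nif3l1, 0.83 for the actin-capping gene Tmod2 and 1.43 for Sh3d19. It was 0.39 for the tight junction gene Cgn, 0.36 for Efcab11 and 0.33 for the metal-responsive factor gene Mtf1.

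The 12 genes lower with TubA included mt-Nd3, mt-Nd4, mt-Nd4l and mt-Nd5. Dpf3, a subunit of the BAF chromatin remodelling complex (chromosome 12, 83213745 to 83487716), stood at 342 ± 78.4 and 195 ± 28.2 TPM (log2 difference -0.79, limma unadjusted p = 0.0012). H2afz, encoding the histone variant H2A.Z, stood at 74.5 ± 10.2 and 46.6 ± 11.8 TPM. The ubiquitin ligase adaptor gene Wsb1 stood at 87.4 ± 17.0 and 53.1 ± 12.1 TPM and Ccser1 at 140.3 ± 22.2 and 93.7 ± 15.1 TPM. Fam110b stood at 30.6 ± 4.94 and 18.5 ± 2.58 TPM and Spsb4 at 17.1 ± 4.17 and 10.002 ± 1.61 TPM. Gapdh, encoding a glycolytic enzyme, stood at 136 ± 72.5 and 44.6 ± 2.94 TPM (log2 difference -1.41). Rps2, encoding a protein of the small ribosomal subunit, stood at 117 ± 115 and 0.885 ± 0.340 TPM (log2 difference -4.50). Gapdh and Rps2 share most of their sequence words with other listed genes (79.8% and 85.3%). Summed with these copies, Gapdh stood at 407.9 ± 78.3 and 337.9 ± 105.5 TPM, within the spread between libraries (exact two-sided permutation p = 0.30). Summed likewise, Rps2 stood at 507.1 ± 213.7 and 491.5 ± 96.6 TPM (exact two-sided permutation p = 0.88). H2afz (59.9%), Dppa2 (32.7%) and Cgn (24.4%) also share sequence words with other genes. Summed with copies, H2afz had a log2 difference of -0.62 (-0.69 alone) and Cgn of 0.35 (0.39 alone), still without overlap between groups, while Dppa2 had 0.46 (0.52 alone) with overlap (exact two-sided permutation p = 0.056).

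The libraries also fell into 2 sets that cross the treatment. Clustering put control replicates 1 to 3 with TubA replicates 1 and 2 (set A), and control replicates 4 and 5 with TubA replicates 3 to 5 (set B). H2-T10, a class I histocompatibility gene, ranged from 52.0 to 107.7 TPM in set A and from 0.0157 to 0.149 TPM in set B. Tex15, a germ cell gene, ranged from 24.1 to 70.1 TPM in set A and from 0.360 to 0.737 TPM in set B. The predicted gene Gm7995 reached at most 0.00610 TPM in set A and at least 38.4 TPM in set B. These 3 genes were chosen after their values were seen. With the set as a term in the limma fit, Rpl36-ps1 was again the 1 gene past the threshold for TubA. Its log2 difference was 2.80 over all libraries, 3.17 within set A and 2.56 within set B. The pseudocount sets this size, as control was listed at 0. Over all libraries it was 5.91 with a pseudocount of 0.1 and 9.21 with 0.01. The 5 libraries of each set left Rpl36-ps1 short of the threshold in sets A and B (limma adjusted p = 0.063 and 0.9999, unadjusted p = 0.00014 and 0.00052). Within set A alone 12 passed (3 control and 2 TubA libraries, 5 higher and 7 lower). The labels name no animal, so differences between animals are not excluded within set A, where genes such as Gm13103, chosen after its values were seen, were on in 1 group and off in the other (at most 0.114 TPM in control and 104.0 to 115.8 TPM with TubA). Within set B alone 0 passed (limma, 199 at an unadjusted p under 0.05). A limma test of whether the TubA difference itself depended on the set passed for 14 genes, in sets found from the same values. Differences between animals within set A could give such calls too, so they are not shown to be an effect of TubA. The mitochondrially encoded genes had a median log2 difference of -0.82 within set A, -0.50 within set B and -0.50 with the set as a term. Camera with the preset correlation passed in each (adjusted p = 5.4e-09, 1.0e-05 and 1.5e-13). None of these calls held when the correlation was estimated (adjusted p = 0.97, 0.98 and 0.61 with an estimated correlation).

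**Figure D2:**
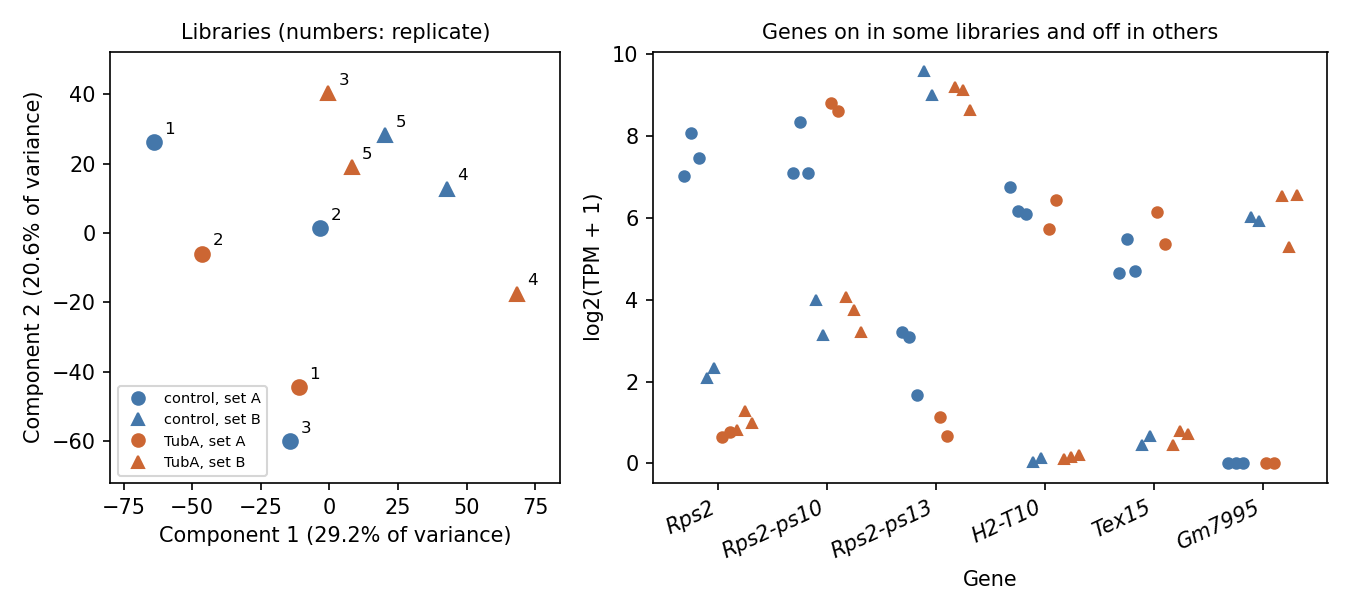
Left, the 10 libraries on the leading principal components of log2(TPM + 1), with the share of variance on each axis (29.2% and 20.6%) and replicate numbers beside the points. Right, log2(TPM + 1) of 6 genes in each library, coloured by group and shaped by library set, where H2-T10 and Tex15 are high in set A and Gm7995 and Rps2-ps13 in set B.

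The other 31 lists did not pass camera over all libraries, and no member of any list passed over all genes tested. The apoptosis list came nearest (23 genes, 18 negative, median log2 difference -0.17, camera adjusted p = 0.10). Of it, 1 gene was lower when adjusted over the list alone, Pmaip1, which encodes the cell death protein Noxa. Pmaip1 stood at 1.92 ± 0.841 and 0.210 ± 0.155 TPM (limma, list adjusted p = 0.046). The abundant members of the list, Bcl2l10 and Birc3, stood at 16482 ± 4238 and 15700.4 ± 4233 TPM and 1193 ± 155 and 1135 ± 198 TPM. In every list other than these 2, the count adjusted over the list alone was 0. Markers of other cell types did not separate the groups either. The 9 cumulus and granulosa genes had a median of -0.22 (camera adjusted p = 0.55). The 8 theca and stroma genes had -0.07 and the 8 blood, immune and endothelial genes -0.01 (camera adjusted p = 0.92 for each). Serpine2 stood at 1667 ± 394 and 1762 ± 436 TPM and Gata4 at 58.5 ± 12.7 and 39.0 ± 7.67 TPM. Dcn stood at 6.89 ± 5.39 and 6.34 ± 4.095 TPM and Bgn at 3.57 ± 2.29 and 5.07 ± 2.23 TPM. Pecam1 stood at 26.4 ± 10.6 and 25.7 ± 5.69 TPM and C1qb at 18.3 ± 14.8 and 20.03 ± 19.5 TPM.

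Genes of the oocyte programme did not pass as lists over all libraries. The 23 oocyte identity genes had a median log2 difference of -0.07. H1foo stood at 14869 ± 2606 and 13734 ± 1965 TPM. H1foo is the linker histone of oocytes. The 20 maternal effect genes had a median log2 difference of 0.10. Zbed3 stood at 18748 ± 4436 and 17056 ± 3629 TPM and Khdc3 at 2660.1 ± 1992 and 3251 ± 2311 TPM. For maternal mRNA decay, 48 genes had a median of -0.06. The deadenylase adaptor gene Btg4 stood at 10332 ± 2156 and 9972 ± 2371 TPM and Cnot7 at 1055 ± 288 and 1053 ± 314 TPM. For meiotic resumption and arrest, 37 genes had a median of 0.01. Ccnb1, encoding cyclin B1, stood at 1609 ± 186 and 1689 ± 212 TPM. For calcium and egg activation, 24 genes had a median of -0.05. Astl stood at 1235 ± 387 and 1154 ± 308 TPM and Rgs2 at 1069.7 ± 249.9 and 987 ± 253 TPM. Within set B alone this list had a median of -0.21 and passed camera with the preset correlation (adjusted p = 0.043) but not with an estimated correlation (adjusted p = 0.98). The 13 early embryo factors had a median of 0.0030. Obox5 stood at 1794 ± 335 and 1900.0 ± 382 TPM and Obox2 at 855 ± 259.9 and 915 ± 313 TPM. The 6 genes tested of those that switch on at the 2-cell stage had a median of 0.0079. Tcstv1 stood at 145 ± 54.3 and 127 ± 71.7 TPM and Sp110 at 102 ± 21.002 and 106 ± 52.9 TPM.

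The cytoskeletal and division lists, tubulins included, did not pass either. The 34 tubulin genes had a median log2 difference of 0.06. Tubg2 stood at 206 ± 157 and 268 ± 140.4 TPM. Tubg2, encoding a gamma-tubulin, lay between 77.0 and 148.7 TPM in set A and between 335.5 and 394.5 TPM in set B. For spindle assembly, 45 genes had a median of 0.07. Pcnt stood at 801 ± 117 and 901 ± 213 TPM and Haus3 at 636 ± 125 and 628 ± 84.7 TPM. For the kinetochore, 41 genes had a median of 0.07. Birc5 stood at 1301 ± 515 and 1449 ± 427 TPM and Bub1b at 724 ± 185 and 743 ± 89.4 TPM. For the anaphase promoting complex list, 21 genes had a median of -0.06. Its most abundant members, Skp1a and Cul1, encode subunits of the related SCF ubiquitin ligase and not of this complex. Skp1a stood at 1120.2 ± 419 and 1204 ± 952 TPM and Cul1 at 868 ± 77.3 and 916 ± 76.1 TPM. For cohesin and condensin, 27 genes had a median of -0.03. Pttg1, encoding securin, stood at 3504 ± 1163 and 3653 ± 999 TPM and Smc4 at 1344 ± 177 and 1252 ± 137 TPM. For the actin cortex, 44 genes had a median of -0.01. Rdx, encoding the membrane linker radixin, stood at 4337 ± 923 and 4291 ± 650.0 TPM and Arpc1b at 878 ± 142 and 802 ± 129.5 TPM.

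Chromatin genes did not pass as lists. Deacetylases and sirtuins, 14 genes, had a median log2 difference of 0.01. Sirt4 stood at 164 ± 10.6 and 185 ± 35.1 TPM and Hdac2 at 75.9 ± 17.3 and 71.5 ± 21.2 TPM. Acetyltransferases and bromodomain readers, 20 genes, had a median of -0.00096. Brdt stood at 1198 ± 223 and 1331 ± 169.6 TPM and Naa50 at 252.02 ± 87.0 and 269 ± 55.8 TPM. Histone methylation enzymes, 35 genes, had a median of -0.02. Eed stood at 528 ± 65.2 and 522 ± 76.6 TPM and Ezh2 at 229.6 ± 34.0 and 175 ± 52.0 TPM. DNA methylation genes, 15 in number, had a median of 0.05. Dnmt1, the maintenance methyltransferase gene, stood at 483 ± 273 and 518 ± 209 TPM and Uhrf1 at 279.8 ± 89.3 and 293 ± 115 TPM. Histone genes and variants, 24 genes, had a median of 0.0074. Slbp, encoding the stem-loop binding protein of histone mRNA, stood at 9951 ± 1825 and 10387 ± 945 TPM. DNA damage genes, 30 in number, had a median of 0.08. Trp53bp1 stood at 1031 ± 629.8 and 970.3 ± 418 TPM and Chek1 at 602 ± 72.1 and 595 ± 44.97 TPM.

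Nuclear genes of energy metabolism and protein homeostasis likewise did not pass over all libraries. The 72 nuclear genes of oxidative phosphorylation had a median log2 difference of -0.14. Atp5b stood at 885 ± 103 and 897 ± 98.4 TPM and Cox6a1 at 387 ± 198 and 367 ± 120.0 TPM. Camera with the preset correlation called this list lower without control replicate 1 (median -0.30, adjusted p = 0.0012), without TubA replicate 4 (-0.37, adjusted p = 0.00044), with the set as a term (-0.25, adjusted p = 0.0066), within set B (-0.32, adjusted p = 1.4e-05) and with array weights (-0.43, adjusted p = 1.4e-06). None of these calls held with an estimated correlation (adjusted p between 0.81 and 0.997 with an estimated correlation). Mitochondrial dynamics and DNA maintenance, 30 genes, had a median of 0.07. Mff stood at 1802 ± 438 and 2052 ± 851 TPM and Rhot1 at 493 ± 147 and 527 ± 141 TPM. Antioxidant genes, 29 in number, had a median of -0.09. Prdx1 stood at 3196 ± 635 and 3466 ± 1074 TPM and Txnip at 1296 ± 365 and 1255 ± 221 TPM. Endoplasmic reticulum stress genes, 21 in number, had a median of -0.13. Hsp90b1 stood at 367 ± 145 and 299 ± 117 TPM and Calr at 221 ± 108 and 199.97 ± 136 TPM. Chaperones, 37 genes, had a median of 0.05. Hsp90aa1 stood at 12704 ± 2745 and 11147 ± 1926 TPM and Ahsa1 at 773 ± 121 and 813 ± 107 TPM. Autophagy genes, 34 in number, had a median of 0.04. Ubqln1 stood at 741 ± 209 and 764 ± 139 TPM and Atg5 at 405 ± 13.7 and 417 ± 28.6 TPM. Proteasome genes, 32 in number, had a median of -0.02. Psmd3 stood at 294 ± 36.7 and 278 ± 28.4 TPM and Psmd4 at 269 ± 16.9 and 258 ± 41.1 TPM. Ribosomal protein genes, 72 in number, had a median of -0.07. Rps27l stood at 547 ± 140.1 and 558 ± 232 TPM and Rplp1 at 173 ± 86.6 and 150.2 ± 66.1 TPM. The ribosomal list passed camera with the preset correlation within set B (-0.18, adjusted p = 0.043) and with array weights (-0.27, adjusted p = 0.011), but in neither with an estimated correlation (adjusted p = 0.98 and 0.81). The median, mean and camera direction differed in sign in 8 lists, none of which passed. These were oocyte identity, early embryo factors, histone genes, histone methylation enzymes, acetyltransferases, chaperones, autophagy, and theca and stroma markers.

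**Figure D3:**
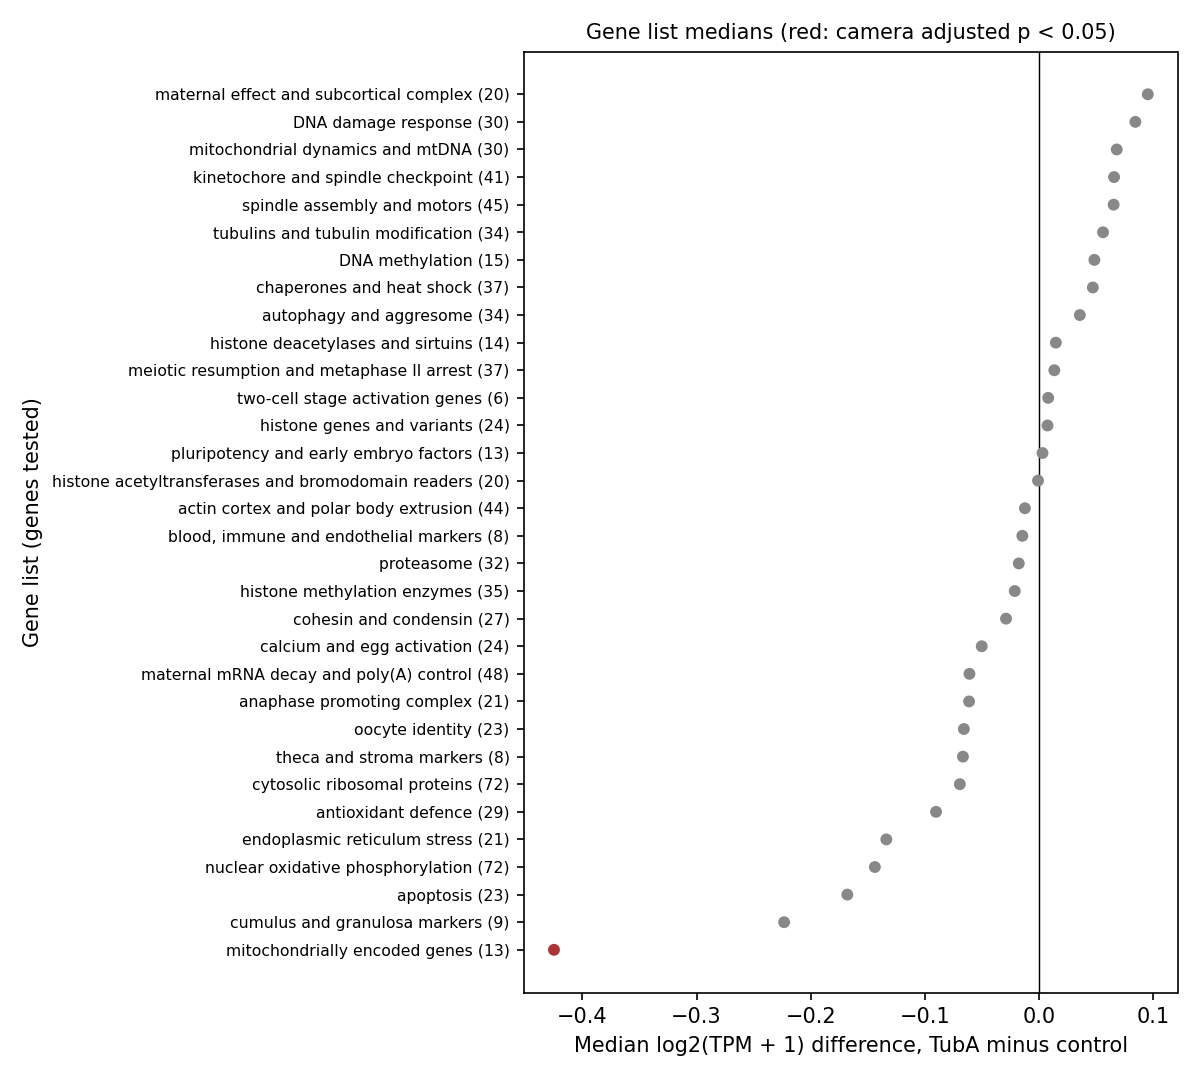
Median log2(TPM + 1) difference, TubA minus control, of each of the 32 gene lists, with the number of genes tested in brackets. The mitochondrially encoded genes (red, median -0.42) are the 1 list past camera with the preset correlation, and grey lists had an adjusted p of 0.10 or more.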

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

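Of 215 groups of 5 libraries examined (library measures and named genes), 19 held a library whose gap to its nearest neighbour was large against the range of its group. Chance flags about 1 in 20 groups of normal values, or 10.8. The groups share the same libraries and TPM need not be normal, so an excess over chance is not shown. No weighing of explanations was made for these values. The values below are those of the library that stood apart, against the range of the other 4 libraries of its group.

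Control replicate 3 stood apart most often. It had more mt-Nd4l (1495 against 504 to 665 TPM), Trp53bp1 (2142 against 580.5 to 847 TPM), Dnmt1 (960.2 against 288 to 445 TPM), Rhot1 (745 against 379 to 480.3 TPM), Naa50 (405 against 194 to 239.5 TPM) and Pecam1 (45.1 against 20.3 to 24.3 TPM), and less mt-Co2 (244 against 501 to 597 TPM). Control replicate 1 had fewer genes at or above 1 TPM (10521 against 11392 to 11677) and less Atp5b (702 against 919 to 946 TPM).

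Among TubA libraries, replicate 4 had more Zp3 (8123 against 749.8 to 2858 TPM), Skp1a (2905 against 727 to 849 TPM), Tubb5 (83.8 against 21.02 to 33.4 TPM), Hdac2 (109 against 55.4 to 67.5 TPM) and C1qb (54.3 against 7.68 to 17.0 TPM). Replicate 1 had more Dnmt1 (881 against 350.4 to 478 TPM), Pold3 (485 against 292 to 342 TPM) and Dnajc7 (96.3 against 49.0 to 55.5 TPM). Replicate 3 had more mt-Nd6 (178 against 68.2 to 97.4 TPM), and replicate 5 had less Psmd4 (186 against 265 to 286 TPM).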

How the results depend on the processing

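The library set, the addition of nuclear copies and the residual component were chosen after seeing the data, and the other alternatives before. The count of 1 gene past an adjusted p of 0.05 (limma), by at least 2-fold and a rise, stayed at 1 with a pseudocount of 0.1 or 0.01, no filter, quantile or median of ratios scaling, array weights, the set as a term, and without each library in turn (range 1 to 1, with 100% of calls a rise). In the runs without a library, the adjusted p of Rpl36-ps1 lay between 0.0056 and 0.020. With a filter at a mean of at least 5 TPM the count was 0 (0 by at least 2-fold, 166 genes at an unadjusted p under 0.05), because the gene falls under the filter. Within set A it was 12 (12 by at least 2-fold, 41.7% a rise), none of them the gene called over all libraries, and within set B 0 (0 by at least 2-fold, 199 unadjusted), with fewer libraries in each. The count at an unadjusted p, 293, ranged from 201 without control replicate 2 to 452 without control replicate 3 and was 549 with no filter, where 22278 genes were tested, 539 with array weights and 452 with the residual component as a term, which is found from the same values and so understates the spread.

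With the replicate block the count was 0 (0 by at least 2-fold, 313 unadjusted), and the adjusted p of Rpl36-ps1 was 0.092 at a log2 difference of 2.80, as without the block. Libraries of equal number had correlations of their deviations of 0.0031, -0.0048, -0.31, 0.48 and 0.26 for numbers 1 to 5. Only those of 4 and 5 correlated best with their own number. In both groups numbers 1 and 2 lay in set A and numbers 4 and 5 in set B. Pairing by number is therefore not shown for all libraries, but a batch that follows the numbers is not excluded. The loss of the Rpl36-ps1 call with the block thus stays a limit of that call. The block left the call of the mitochondrial list in place (adjusted p = 1.2e-08).

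The number of lists past camera, 1, was 0 with an estimated correlation, where the mitochondrial median of -0.42 had an adjusted p of 0.42 as its genes vary together (estimated correlation 0.54). With an estimated correlation it was also 0 with the set as a term, within set A and within set B, where the mitochondrial medians were -0.50, -0.82 and -0.50 (adjusted p = 0.61, 0.97 and 0.98). With the preset correlation it was 2 with the set as a term, 4 within set B and 3 with array weights, and the cause was not tested. It ranged from 1 to 2 without a library, with 2 without control replicate 1 and without TubA replicate 4. The nuclear oxidative phosphorylation list was added in all 5 of these, the ribosomal list within set B and with array weights, and the egg activation list within set B. The mitochondrial median ranged from -0.61 to -0.30 without a library, and camera with the preset correlation passed in each run. The median log2 difference of all genes was at most 0.017 in size under any scaling. The difference in genes detected per library, -119.6 at 1 TPM, was -125.0 at 0.1 TPM. It ranged from -311.05 without control replicate 1 to -6.30 without TubA replicate 2, with exact permutation p from 0.22 to 0.98. Of the 25 named genes of largest change, none changed direction under these settings, and Rps2 passed within set A (limma adjusted p = 0.0010). All 25 had no overlap between groups, so leaving out libraries or taking a set alone could not reverse them. Their constant direction is thus no test of these genes. Thinning and all count-based alternatives did not apply to TPM, and a planned surrogate variable from the sva package was not run. The leading principal component of the residuals (31.8% of their variance), put in its place as a term, left 1 gene and 1 list past the threshold. Since the depth is unknown, what depth limits cannot be stated.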

Other observations

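The tests of other splits, of the mitochondrial genes and of Rps2 were chosen after the values were seen, and those of Gapdh, of neighbouring genes and of GC content and length were stated before their results were seen. Some genes told apart smaller groups of libraries than the treatment, all named after their values were seen. Cbx3, encoding the heterochromatin protein HP1 gamma, lay between 181.9 and 241.8 TPM in control replicates 1 to 3 and between 120.6 and 191.0 TPM in set B, but at 0.863 and 0.383 TPM in TubA replicates 1 and 2. The predicted gene Gm6768 lay between 184.2 and 287.7 TPM in control replicates 1 to 3 and under 1 TPM in every other library. Pcp4l1 and the peroxisomal carrier gene Slc25a17 reached 143.0 and 186.3 TPM, and 74.4 and 86.8 TPM, in TubA replicates 1 and 2, against at most 4.43 and 12.1 TPM in the other libraries. Oas1d, an oocyte gene, ranged from 3266 to 5015 TPM in set A and from 940.3 to 1582 TPM in set B, and Ddx4, a germ cell helicase gene, from 222.3 to 709.2 TPM and from 25.2 to 100.8 TPM.

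Chance cannot be excluded for the count of genes or the count of lists. Of 100 splits of the 10 libraries into 5 and 5 (of 126 possible, the real one included), 9 called as many genes as the real split, which called 1, and the highest of the others called 237. That split is the one between the library sets. Since the sets were found from the same values, its high count is no independent sign of a structure of the libraries. Of the same splits, 78 called as many gene lists as the real one, which called 1, and the highest of the others called 11. In 6 of the 100 the mitochondrial list had a camera p as small as the real one.

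The lower mitochondrial transcripts with TubA, at a median of -1.02 log2 units for the 6 genes from mt-Nd3 to mt-Cytb against -0.20 for the 7 from mt-Nd1 to mt-Co3, were set against 3 technical explanations. Reads shared with nuclear copies of mitochondrial DNA are argued against, since the median of the 6 genes was -0.996 with the copies added (-0.20 for the other 7) and the 3 genes without a copy lay at -0.77 or below. Scaling of each library to a fixed total, which moves all genes of a library alike, is argued against, since the log2 median of ratios factor over 12409 genes was 0.036 ± 0.147 in control and 0.028 ± 0.112 with TubA (SD, n = 5 each), a difference of -0.0078 (SE 0.083), against a median of -0.42 for all 13 mitochondrially encoded genes. For the library sets, the mean difference of the 6 genes was -0.83 within set B and -1.03 with the set as a term. It was -1.23 within set A, where animals may differ between the groups. The 6 genes were picked for low values in these same libraries, and mt-Nd3, mt-Nd4l, mt-Nd4 and mt-Nd5 had no overlap between groups. A lower mean within each set was thus largely given and decides nothing about the sets. The list of all 13 genes was fixed before the data were examined. Its median was -0.82 within set A, -0.50 within set B and -0.50 with the set as a term. None of these passed camera with an estimated correlation. An effect of TubA, the library sets, differences between animals, and chance, given the splits above and a division of the genes found from these values, all stay open.

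The 2 sets of libraries may reflect oocytes from animals with different genomes, as ICR is an outbred stock. Of the 237 genes called between the sets, a count that is not an independent test because the sets were found from the same values, 15 neighbouring pairs on the chromosomes differed in the same direction, against a median of 2 over 10000 random draws (one-sided permutation p = 1e-04, the smallest the draws can give). Of pairs whose symbols begin with unlike characters there were 10 (median 2 in draws, one-sided permutation p = 0.0002). This leaves out copies named alike, but not all predicted genes, whose numbered symbols can begin unlike. The draws treat genes as independent, so neighbours that vary together for another reason would also give such pairs. The pairs therefore do not tell different genomes from a batch. GC content and length are argued against as the whole cause, since 81.4% of these genes (193) were still called after a smooth trend on both was removed. A batch of library preparation stays open, as the labels give none.

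Rps2 and Gapdh, both lower with TubA, may owe their differences to reads divided among near-identical copies. Alone they differed by -4.50 and -1.41 log2 units, and summed with 30 and 46 copies by 0.043 and -0.30. Rps2 had 129.6 to 270.6 TPM in control replicates 1 to 3, where its copy Rps2-ps10 had 135.4 to 327.7 TPM, Rps2-ps10 had 445.5 and 390.7 TPM in TubA replicates 1 and 2, and the copy Rps2-ps13 had 398.1 to 771.3 TPM in set B. Alleles that match a copy better than the gene would give such a switch, which was not tested, since the files hold no reads.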
